A study of Mus musculus with 6 samples.

How the data were processed

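The series measured messenger RNA in endothelial cells of the mouse retina. Per the labels, C57BL/6 pups carried Rnf20 alleles that can be deleted by Pdgfb-CreERT2, a tamoxifen-inducible recombinase active in endothelium, and received 75 µg of 4-hydroxytamoxifen each day from postnatal day 1 to day 4. Retinas were taken at day 7 and digested with collagenase, and cells carrying CD31, a surface protein of endothelium that platelets and some leukocytes also carry, were sorted. The 3 pups without the recombinase form the Ctrl group and the 3 with it the KO group, and the source names give a different pup for each library. Per the labels' protocols, polyadenylated RNA was reverse transcribed and amplified as full-length cDNA from very low input, fragmented by tagmentation and sequenced on a BGISEQ-500 as single reads of 50 bases. This preparation does not mark the strand. The labels give no batch, litter or sex.

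The submitters' processing notes name Trimmomatic 0.36, STAR, DESeq2, edgeR, deepTools and the mouse build mm10, with no role or order. The tool that counted the reads and the annotation release are not given in the sources used here. The deposited table holds 34035 RefSeq transcript entries under 19124 gene symbols. Per the file headers and the values, the authors gave raw counts of each library, normalized counts (a signal that equals the count divided by 1 DESeq2 size factor for each library) and RPKM (counts scaled by length and depth). The authors' table further holds a length, the log2 fold change of KO over Ctrl with its standard error, a Wald statistic (a score), and a p-value with an adjusted p-value, all named in the deposited header. One count column of the Ctrl group carried a name unlike its replicate number. It was taken as Ctrl 3 because the other columns of the group matched their normalized columns by name, and its ratio of count to normalized count is 1 constant. No column of per-sample values was left unused.

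The length in the deposited table is the stretch from transcript start to end on the genome: 80.4% of the genes matched to the reference lay within 2% of that span, and the median ratio of the length to the exonic length was 5.25. RPKM values therefore understate long genes with long introns, and no comparison here uses them. Of 23 genes nested in an intron of another gene and holding over 5000 counts, the host entry held at least 95% of the nested gene's counts in 20, so reads in introns and nested genes entered the host's count. In the Ctrl libraries Xist and its antisense partner Tsix had nearly the same counts, so strand was not used. Of the matched genes, 28.2% overlap another gene of the table, and their counts are uncertain. Symbols with more than 1 transcript entry numbered 7198, and 9236 entries repeated the counts of another entry of their symbol.

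To count each gene once, the entry with the longest span of each symbol was used. This choice was made after the table was seen and before any model was fitted. Accessions matched the RefSeq annotation of GRCm38.p6, the assembly of mm10, for 33907 entries and 19043 genes. Coordinates are from that annotation, 1-based. Transcript GC content and exonic length were taken from GENCODE M21, which gave a GC value for 97.7% of tested genes.

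KO was compared with Ctrl by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization, the filterByExpr filter, no covariate, Benjamini-Hochberg adjustment over 16217 genes and a two-sided threshold of 0.05. The standard error given with a log2 fold change is its size divided by the square root of the test's F statistic. Levels are CPM (counts scaled to library size) with TMM scaling, as mean ± SD over 3 libraries. With 3 against 3, an exact permutation test cannot give a two-sided p below 0.1. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 37 lists of at least 3 tested members. Camera compares the members with all other genes. It was repeated with an estimated correlation, and fry, which tests whether the members moved one way on balance without comparing them with other genes, was run beside it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the summaries and plots.

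The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes 17 genes tied to the question, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a named symbol, and up to 4 members of each list with the smallest adjusted p. At most 3 members of a list were named, all past the threshold. That limit was set after the values were seen, in part to shorten the account of alternatives, while counts cover all members. Angpt1, Jam2, Cyp1b1, Trp53inp1, Rn45s, Pou4f1, Slc17a6 and Sag were named outside the rule, after their values were seen. The level of 1 further gene is not reported here. The lists come from general knowledge, and some genes stand in several of them.

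Alternatives were RLE or upper-quartile scaling, no low-count filter or at least 5 CPM in 3 libraries, a robust dispersion, DESeq2 1.42.0, limma-voom, a log2 change of at least 1, the replicate number as a block, each library left out in turn, and exonic length. Alternatives chosen after seeing the data were all transcript entries, the entry with the highest count, chromosomes other than X and Y, genes that overlap no other gene, libraries scaled to equal endothelial markers, the endothelial or photoreceptor marker level as a covariate, and offsets that remove each library's trend with GC content (lowess, span 0.3), alone and with that scaling. Rnf20 was also left out of the list that holds it. Errors in the GC offsets and in the choice of chromosomes were corrected after first results were seen. The correction of the GC offsets left each verdict as it was. A planned change of pseudocount did not apply because the values are counts.

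The code was tested on 10 simulations of KO against Ctrl over 16217 genes, each with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 0.4% of the 2-fold and 38.1% of the 4-fold changes, and 31 of 416 calls (7.45%) were false. An earlier requirement of more than 50% recovered was not met and was replaced by these values. In a separate simulation a planted list was called, and 0 of the 36 other lists were. Genes were drawn independently there, while the estimated correlation in the data reached 0.81 (photoreceptor list). It therefore does not test camera's calls of lists with correlated genes. Libraries held 14581701 to 30692948 counts with 1 entry per gene, and 3 counts, the floor used for a gene with none, corresponded to 0.103 to 0.196 CPM with TMM scaling. Reads carry no molecular identifiers, so floors cover counting error only. Libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of 16.7 to 337, so none was taken for a repeat.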

Results

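RNA from CD31-sorted retinal cells of 6 pups was compared at postnatal day 7, when the retinal vessels are still sprouting. Each of the 3 Ctrl and 3 KO libraries came from a different pup. With 1 transcript entry per gene, Ctrl 1, 2 and 3 held 28969300, 22677108 and 14581701 counts. KO 1, 2 and 3 held 25016982, 27726249 and 30692948. The 10 most abundant genes took between 4.00% and 7.43% of each library's counts. The series title names the question: how the amount of Rnf20, an E3 ubiquitin ligase that modifies histone H2B together with Rnf40, bears on VEGF and Notch signalling in sprouting vessels.

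The targeted gene Rnf20 (NM_001163263, chromosome 4, 49632005 to 49656887, plus strand, GRCm38.p6) was lower in each KO library than in each Ctrl library. Its level was 47.9, 57.1 and 56.8 CPM in Ctrl 1, 2 and 3 and 39.1, 31.0 and 31.7 CPM in KO 1, 2 and 3, from 778 to 1403 counts per library. The mean was 53.9 ± 5.18 CPM in Ctrl and 33.9 ± 4.48 CPM in KO (SD, n = 3 each). This is a ratio of Ctrl to KO of 1.59 and a log2 fold change of −0.67 (SE 0.235). The change did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.101). The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Without KO 1 the log2 fold change was −0.71 and passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0373, range 0.00456 to 0.309 over 22 alternatives, of which it passed 3). The others it passed were libraries scaled to equal endothelial markers (−1.83) and that scaling with GC offsets (−1.72). These moved the median of all genes to −1.16 and −1.18. The labels do not say which part of the gene was deleted and the counts cover its whole span, so transcripts lacking the deleted part are still counted. Rnf40, its partner, had a log2 fold change of −0.44, and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.374).

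**Figure D1:**
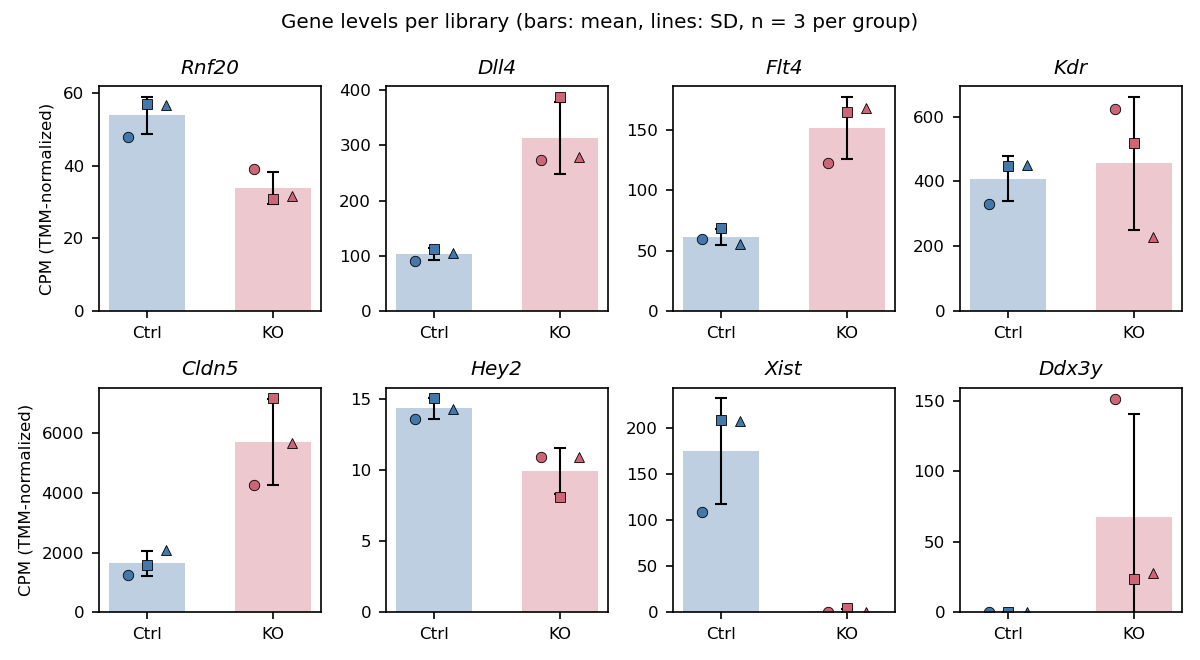
Level of 8 genes in each library, in CPM with TMM scaling, with points for single libraries, bars for the group mean and lines for the SD (n = 3 per group). Rnf20 was lower in each KO library than in each Ctrl library, Dll4, Flt4 and Cldn5 were higher, Kdr and Hey2 did not pass the test, and Xist and Ddx3y separated the groups.

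Among 16217 genes, 948 were higher and 720 lower in KO (1668 in all, 56.8% of them higher) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Outside the sex chromosomes and the globin genes, the largest rises were in C1ql1, a secreted C1q-domain protein (log2 fold change 3.92 ± 0.624 SE, chromosome 11), Timd2, a ferritin receptor (3.30 ± 0.507, chromosome 11), the interferon-induced chemokine Cxcl10 (3.25 ± 0.620, chromosome 5) and the transcription factor Cebpb (3.21 ± 0.762, chromosome 2). The largest falls outside the X chromosome were in Slitrk6, a synaptic adhesion protein (−3.89 ± 0.385, chromosome 14), the meiotic helicase Hfm1 (−3.05 ± 0.643, chromosome 5) and Zfp558 (−2.71 ± 0.435, chromosome 9). They were followed by Cngb3, a channel subunit of cones (−2.50 ± 0.356, chromosome 4), Gje1 (−2.46 ± 0.482, chromosome 10), Impg2, a proteoglycan of the matrix around photoreceptors (−2.43 ± 0.234, chromosome 16), Bmp3 (−2.39 ± 0.328, chromosome 5) and Zfp763 (−2.30 ± 0.347, chromosome 17). Impg2 dropped from 339 ± 23.5 to 63.1 ± 8.05 CPM, and Slitrk6 from 18.3 ± 4.07 to 1.23 ± 0.288 CPM (SD, n = 3). These were taken from 1496 genes that met the naming criteria, 842 higher and 654 lower.

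The count of genes past the threshold changed with the library left out. Such fits have fewer libraries to measure spread, so a count of 0 does not show that the result rested on 1 library. Without Ctrl 1, Ctrl 2, Ctrl 3 or KO 2, 0 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while 4005, 3434, 3479 and 3576 genes had an unadjusted p below 0.05, against 4953 with all libraries (as genes changed between KO and Ctrl in all 6 libraries, DESeq2 called 3556 and limma-voom 1910). Without KO 1, 4927 genes passed (2520 higher, 2407 lower), which included 1667 of the 1668, and without KO 3, 866 passed (499 higher, 367 lower), 767 of them among the 1668. Values of the 2 groups did not overlap for 37.9% of genes, where chance gives 10%. The share of higher genes was 44.4% with GC offsets, 1.17% with libraries scaled to equal endothelial markers, which moved the median of all genes to −1.16, and 0.748% with both, which moved it to −1.18. Of the called genes, 25.5% overlap another gene, so that their counts are uncertain. Among the genes named here this holds for Xist (Tsix), Cxcl10 (Art3), Angpt2 (Mcph1), Gje1, Cdc20 (Elovl1), E2f1 (Necab3), Gins2 (Gse1), Ptbp1 (Plppr3), Dll4, Notch1, Tmem252, Eng, Nos3, H19, Igf2, Peg3, Egfl7, Des, Glul, Pax2, Prox1 and Plvap.

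Marker lists showed which cells contributed RNA. The 15 endothelial markers were higher in KO, at a mean of 8.68 ± 0.302 log2 CPM against 7.51 ± 0.361 in Ctrl (SD, n = 3, exact permutation p = 0.1, the smallest possible), and each KO library (8.89, 8.82 and 8.33) lay above each Ctrl library (7.10, 7.72 and 7.73). Of them 9 rose and 0 fell (12 and 0 adjusted over the list alone), among them Erg, a transcription factor of endothelium (log2 fold change 1.63), Ramp2 (1.65) and Egfl7 (1.67). Pecam1, which encodes the sorted protein CD31, had a log2 fold change of 0.83 and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.142). Photoreceptor RNA was abundant in the sorted cells. Sag, the rod arrestin, reached 14089, 6136 and 7310 CPM in Ctrl 1, 2 and 3 and 1499, 3183 and 7135 CPM in KO 1, 2 and 3, and was the most abundant gene of each Ctrl library. The 14 photoreceptor markers averaged 10.3, 9.70 and 9.89 log2 CPM in Ctrl 1, 2 and 3 and 7.66, 8.66 and 9.93 in KO 1, 2 and 3 (exact permutation p = 0.3). Gngt1 (−1.84) and Pde6b (−1.73), parts of the rod transduction cascade, fell. With GC offsets the log2 fold change was −0.91 for Gngt1 (transcript GC content 36.7%) and −1.76 for Pde6b (49.8%). Camera called the endothelial list (mean 1.10 log2 units above other genes, adjusted p = 6.99e-07) and the photoreceptor list (−1.03, 0 up and 2 down, 0 and 3 adjusted over the list alone, adjusted p = 0.000924). With an estimated correlation these gave adjusted p = 0.308 (4.61e-08 to 0.871 over 22 alternatives) and adjusted p = 0.441 (1.42e-07 to 0.682), and without KO 1 camera gave the photoreceptor list an adjusted p = 0.0624 at −0.60.

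Some markers of inner retinal neurons fell. Of these 15 markers 0 rose and 3 fell (0 and 5 adjusted over the list alone): Snap25, a synaptic fusion protein (log2 fold change −1.71), Otx2 (−1.48) and Trpm1, a channel of bipolar cells (−1.20). Camera placed the list at −0.71 against other genes (adjusted p = 0.00601, adjusted p = 0.383 with an estimated correlation, 0.000551 to 0.880 over 22 alternatives). Retinal ganglion cell markers rose as a list, with 2 of 8 up and 0 down (3 and 0 adjusted over the list alone), Sncg (2.72) and Rbpms (1.77), but 2 of the 8 estimates were negative, Pou4f1 (−1.28) and Slc17a6 (−0.44), neither past the threshold. Camera gave that list a mean of 0.89 and an adjusted p = 0.0304 (adjusted p = 0.308 with an estimated correlation, 0.000384 to 0.308 over 22 alternatives), which became 0.0711 without KO 1 and 0.0591 without KO 2. Mural cell markers rose by 1.18 as a list in camera (adjusted p = 0.00523, adjusted p = 0.410 with an estimated correlation, 8.14e-06 to 0.410 over 22 alternatives), with only Des, an intermediate filament of pericytes and muscle, past the threshold of 12 (2.10) and 0 adjusted over the list alone.

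Blood cell transcripts moved with the genotype too. The globin genes rose about together, with Hba-a1 and Hba-a2 at 23.6 ± 6.82 CPM in Ctrl and 168 ± 29.6 CPM in KO (log2 fold change 2.83 each, SD, n = 3) and Hbb-bs and Hbb-b1 at 3.08. The paralogs share reads, so the 6 of 7 erythroid markers that rose (6 and 0 down adjusted over the list alone) are not separate measurements. Camera gave the erythroid list a mean of 2.58 (adjusted p = 6.99e-07, adjusted p = 0.308 with an estimated correlation, 6.11e-14 to 0.308 over 22 alternatives). Of 6 platelet markers 2 rose and 0 fell (4 and 0 adjusted over the list alone), Pf4 (1.92) and Nrgn (1.62), and camera gave a mean of 1.19 (adjusted p = 0.00635, adjusted p = 0.308 with an estimated correlation, 0.00188 to 0.308 over 22 alternatives). Microglial markers averaged 1.95 above other genes with 0 of 14 past edgeR's threshold (0 adjusted over the list alone, 1 at an unadjusted p below 0.05, 1 by DESeq2, 0 by limma-voom), and camera did not call them (adjusted p = 0.149). Their mean level was 5.46, 5.95 and 3.38 log2 CPM in Ctrl 1, 2 and 3 and 3.05, 8.56 and 6.29 in KO 1, 2 and 3, and the mean difference was 0.25 without KO 2. Camera called them without Ctrl 2 (2.37, adjusted p = 0.0256) and without KO 1 (2.51, adjusted p = 0.00127), within a range of 1.01e-05 to 0.821 over 22 alternatives. With all libraries and an estimated correlation camera gave an adjusted p = 0.707.

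Other cell types were not called by camera. Müller glia and astrocyte markers had 2 of 12 up and 0 down (3 and 0 adjusted over the list alone, mean 0.36, adjusted p = 0.259), with Pax2, a transcription factor of astrocytes (2.12), and Glul, a glial enzyme (1.34). Retinal progenitor markers had 0 of 8 past edgeR's threshold (0 adjusted over the list alone, 1 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom, mean −0.12, adjusted p = 0.969), and their mean was 0.08 without Ctrl 1 and 0.07 without KO 2. Lymphatic markers had 0 up and 2 down of 5 (1 and 2 adjusted over the list alone, mean −0.11, adjusted p = 0.616), Prox1 (−1.40) and Reln (−1.31), both of which retinal neurons also express. The pigment epithelium and choroid markers had 1 of 7 up and 0 down (1 and 0 adjusted over the list alone, mean 0.81, adjusted p = 0.190), the fenestration gene Plvap (1.31).

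**Figure D2:**
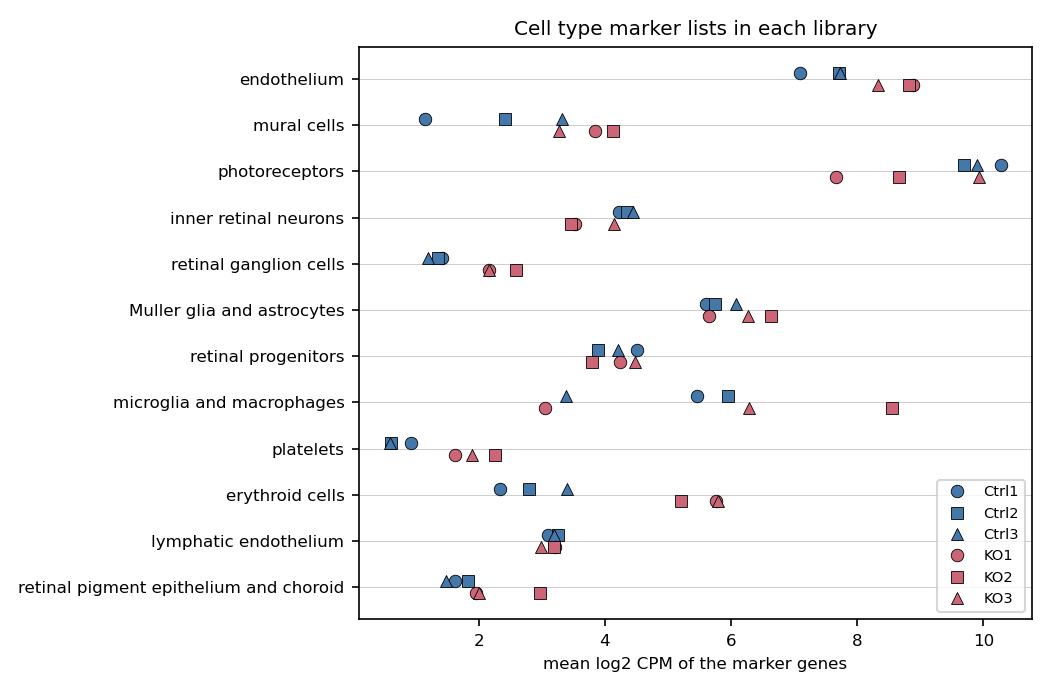
Mean log2 CPM of the genes of each cell type marker list, with 1 point for each of the 3 Ctrl (blue) and 3 KO (red) libraries and a marker shape for each replicate. Endothelial markers were at 8.33 to 8.89 in KO and 7.10 to 7.73 in Ctrl, and photoreceptor markers were lowest in KO 1 (7.66).

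Some VEGF and Notch genes rose, as did endothelial markers (1.10 above other genes as a list). Dll4, the Notch ligand of sprouting tip cells (NM_019454, chromosome 2, 119325784 to 119335666), was 3.05-fold higher, from 103 ± 10.8 to 313 ± 65.0 CPM (SD, n = 3). Flt4, the receptor VEGFR3 (NM_008029, chromosome 11, 49609679 to 49652739), was 2.48-fold higher, from 61.3 ± 6.65 to 152 ± 25.7 CPM. Both passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0212 and 0.0231), as did the Notch ligand Jag2 (log2 fold change 1.51) and Mfng, a glycosyltransferase acting on Notch (1.06). Kdr, the main VEGF receptor of endothelium, had a log2 fold change of 0.16 ± 0.378 (SE) and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.807). Neither did the ligand Vegfa (0.69), the decoy receptor Flt1 (0.85), Notch1 (0.82), Nrarp (1.52), Jag1 (0.48) or the Notch targets Hey1 (0.50) and Hey2 (−0.53), with adjusted p from 0.0673 to 0.575. The Dll4 log2 fold change was 1.52, 1.67, 1.62 and 1.45 without Ctrl 1, Ctrl 2, Ctrl 3 and KO 2, where it did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0801, 0.112, 0.107 and 0.0859, range 3.93e-06 to 0.896 over 21 alternatives), and no other gene did.

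As lists, VEGF ligands and receptors had 1 of 9 up and 0 down (1 and 0 adjusted over the list alone), and camera gave a mean of 0.78 above other genes (adjusted p = 0.00257, adjusted p = 0.308 with an estimated correlation, 0.000388 to 0.887 over 22 alternatives). Of 24 Notch pathway genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), and camera gave 0.31 (adjusted p = 0.0302, adjusted p = 0.376 with an estimated correlation, 0.00627 to 0.743 over 22 alternatives). The Notch pathway list was not called without KO 1 (0.28, adjusted p = 0.0670) or with GC offsets (0.13, adjusted p = 0.228).

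**Figure D3:**
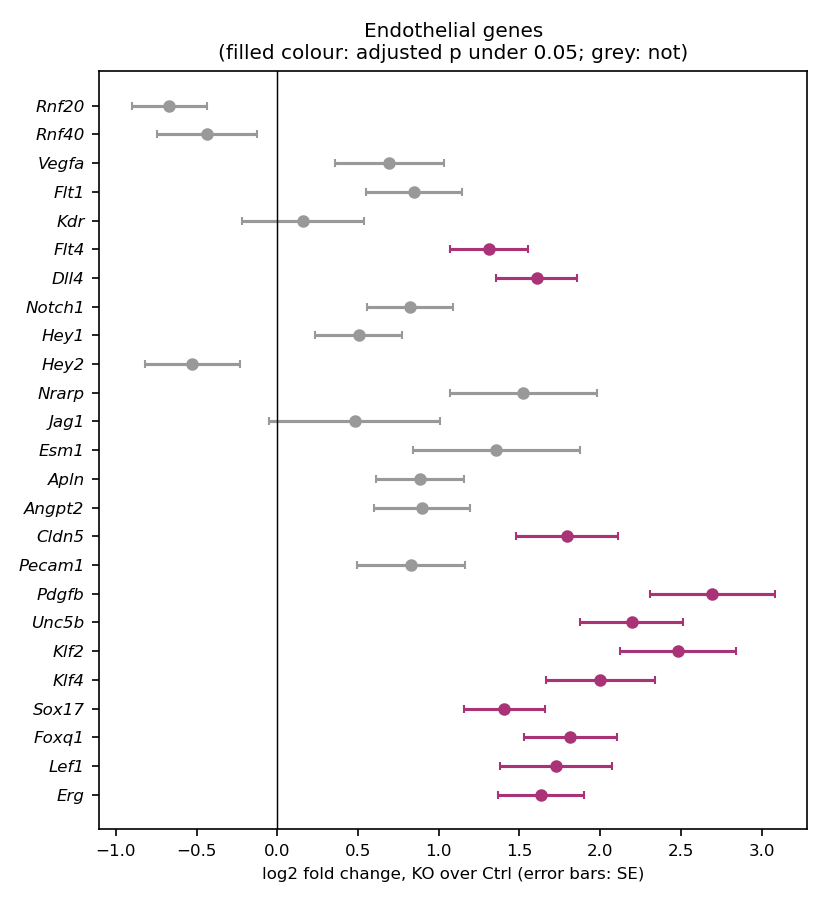
Log2 fold change of KO over Ctrl with its standard error for genes of endothelium, VEGF and Notch signalling. Coloured points passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as Dll4 (1.61) and Pdgfb (2.69) did, and grey points such as Kdr (0.16) and Rnf20 (−0.67) did not.

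Among genes of specialised endothelium, some of those of tip cells, arteries, veins and the barrier rose in KO and 0 fell. Of 19 tip cell genes 6 rose and 0 fell (13 and 0 adjusted over the list alone), with Pdgfb, the growth factor that recruits pericytes, 6.47-fold higher (log2 fold change 2.69 ± 0.388 SE) and the netrin receptor Unc5b at 2.20 ± 0.318. Esm1 (1.36), Apln (0.88) and Angpt2 (0.89) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.124, 0.0728 and 0.0874). Arterial genes had 5 of 16 up and 0 down (6 and 0 adjusted over the list alone), among them the gap junction gene Gja4 (2.12) and the transcription factor Sox17 (1.40). Venous genes had 3 of 11 up and 0 down (5 and 0 adjusted over the list alone), among them the ephrin receptor Ephb4 (1.61) and Tmem252 (1.24). Barrier genes had 7 of 20 up and 0 down (10 and 0 adjusted over the list alone). Cldn5, the tight junction protein (NM_013805, chromosome 16, 18776847 to 18778262), was 3.47-fold higher, from 1646 ± 419 to 5711 ± 1451 CPM (SD, n = 3), and the transcription factors Foxq1 (1.81) and Foxf2 (1.76) rose with it. Camera called all 4 lists. It gave 1.04 for tip cell genes (adjusted p = 6.99e-07, adjusted p = 0.308 with an estimated correlation, 2.28e-08 to 0.389 over 22 alternatives) and 0.97 for arterial genes (adjusted p = 0.000394, adjusted p = 0.308 with an estimated correlation, 9.19e-05 to 0.308). It gave 0.79 for venous genes (adjusted p = 0.00122, adjusted p = 0.376 with an estimated correlation, 0.000244 to 0.685) and 1.00 for barrier genes (adjusted p = 2.43e-06, adjusted p = 0.376 with an estimated correlation, 1.54e-09 to 0.743). The endothelial markers moved with each of these groups, by 1.10.

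Among signalling and matrix genes of vessels more rose than fell, beside endothelial markers at 1.10. Wnt receptors and targets had 4 of 15 up and 0 down (7 and 0 adjusted over the list alone), such as Lef1, a nuclear effector of Wnt (log2 fold change 1.73), and Apcdd1 (1.61), a Wnt target in retinal vessels. BMP and TGF-beta genes had 4 of 18 up and 0 down (9 and 0 adjusted over the list alone), such as the receptors Acvrl1 (1.75) and Eng (1.54). Basement membrane and matrix genes had 8 of 18 up and 0 down (10 and 0 adjusted over the list alone), with perlecan, Hspg2, 5.43-fold higher, Lama5 at 1.95 and Sparc rising from 1941 ± 368 to 6151 ± 581 CPM (SD, n = 3). Of 8 genes that respond to blood flow 5 rose and 1 fell (7 and 1 adjusted over the list alone), with the transcription factors Klf2 (2.48) and Klf4 (2.00) and the nitric oxide synthase Nos3 (1.42) up and Cyp1b1 (−1.22) down. Angiopoietin and junction genes had 6 of 15 up and 2 down (8 and 2 adjusted over the list alone): Esam (1.51), F11r (1.29) and the receptor Tie1 (1.45) were among the former, and Angpt1 (−2.51), the ligand made largely outside endothelium, and Jam2 (−1.04) were the latter. Camera gave the Wnt list 0.92 (adjusted p = 0.000688, adjusted p = 0.308 with an estimated correlation, 0.000237 to 0.647 over 22 alternatives) and the BMP list 0.84 (adjusted p = 0.000688, adjusted p = 0.308 with an estimated correlation, 0.000244 to 0.887). The matrix list stood at 1.20 (camera, adjusted p = 1.14e-06, adjusted p = 0.376 with an estimated correlation, 2.28e-08 to 0.680). The flow list stood at 1.22 (camera, adjusted p = 0.000688, adjusted p = 0.308 with an estimated correlation, 2.31e-05 to 0.553) and the angiopoietin list at 0.52 (camera, adjusted p = 0.00211, adjusted p = 0.383 with an estimated correlation, 0.000461 to 0.647).

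Among lists of inflammatory and stress genes, camera called those of adhesion, interferon and immediate early genes higher in KO, but not the unfolded protein response. The endothelial markers were higher as well (1.10). Microglial markers, whose cells also express many genes of these lists, averaged 1.95, but did not follow the lists in each library. In KO 1 they were at 3.05 log2 CPM, the lowest of the 6 libraries. There the adhesion list was at 6.16, against 3.74, 5.04 and 4.69 in Ctrl 1, 2 and 3. The interferon list was at 3.41 in KO 1, against 1.41, 2.72 and 2.74. Of 15 adhesion and NF-kB genes 9 rose and 0 fell (14 and 0 adjusted over the list alone), with Icam2, a leukocyte adhesion molecule of endothelium (log2 fold change 1.66), Nfkbia, the inhibitor induced by NF-kB (2.05), and the chemokine Cxcl1 (2.35). Of 16 interferon response genes 3 rose and 0 fell (3 and 1 adjusted over the list alone): Bst2 (2.81), Isg15 (2.49) and Ifitm3 (1.90). Of 16 immediate early and stress genes, which tissue dissociation can induce, 4 rose and 0 fell (6 and 0 adjusted over the list alone), among them Hspb1 (2.41), Ier3 (1.73) and Junb (1.35). Camera called the adhesion list at 1.85 (adjusted p = 3.68e-08, adjusted p = 0.308 with an estimated correlation, 4.59e-17 to 0.308 over 22 alternatives). It also called the interferon list at 0.71 (adjusted p = 0.00668, adjusted p = 0.410 with an estimated correlation, 3.24e-05 to 0.871) and the immediate early list at 0.87 (adjusted p = 0.000610, adjusted p = 0.410 with an estimated correlation, 2.02e-05 to 0.410). With GC offsets the immediate early list stood at 0.42 (camera, adjusted p = 0.0180). The interferon list was not called without Ctrl 1 (0.42, adjusted p = 0.0671). The 13 genes of the unfolded protein response had 1 up and 0 down (0 adjusted over the list alone), Sdf2l1 (1.55), and camera gave an adjusted p = 0.969 with its test pointing up at a mean of −0.04.

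Few cell cycle genes passed the threshold. Of 25 mitosis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), Cdc20 (log2 fold change 1.20), Ube2c (1.20) and Birc5 (1.26), and of 22 DNA replication genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), E2f1 (1.96) and Gins2 (1.48). Camera called the mitosis list at 0.40 (adjusted p = 0.0120, adjusted p = 0.704 with an estimated correlation, 2.04e-05 to 0.704 over 22 alternatives) and the replication list at 0.51 (adjusted p = 0.00211, adjusted p = 0.410 with an estimated correlation, 0.000327 to 0.410). The lowest of the mitosis range came from camera with the endothelial marker level as a covariate, where that list was lower in KO (−1.55). The mitosis list was not called without Ctrl 1 (0.09, adjusted p = 0.382) or without KO 1 (0.04, adjusted p = 0.304). Of 20 p53 targets 4 rose and 1 fell (6 and 3 adjusted over the list alone), and camera did not call the list (0.37, adjusted p = 0.190). The cell cycle inhibitor Cdkn1a was 4.64-fold higher, from 239 ± 7.39 to 1110 ± 324 CPM (SD, n = 3). The pro-apoptotic gene Bbc3 (1.45) and the stress cytokine Gdf15 (2.48) rose, and Trp53inp1 fell (−1.82). The endothelial markers moved with these groups as well, by 1.10.

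Genes of the machinery around Rnf20 were tested together with Rnf20 itself. Of 15 genes of H2B ubiquitination and the PAF1 complex, Rnf20 among them, 0 rose and 1 fell (0 and 1 adjusted over the list alone): Ctr9, a PAF1 subunit, dropped from 181 ± 3.45 to 78.3 ± 6.21 CPM (log2 fold change −1.21 ± 0.212 SE, SD of levels, n = 3). Camera gave the list −0.42 (adjusted p = 0.0465, adjusted p = 0.308 with an estimated correlation, 0.0155 to 0.308 over 23 alternatives). With Rnf20 left out the list was not called (−0.40, camera, adjusted p = 0.0786). Camera did not call the list of 15 without Ctrl 1 (−0.44, adjusted p = 0.0673), Ctrl 3 (−0.44, adjusted p = 0.0605), KO 2 (−0.30, adjusted p = 0.121) or KO 3 (−0.35, adjusted p = 0.119), nor with GC offsets (−0.30, adjusted p = 0.140). Endothelial markers moved the other way (1.10) and photoreceptor markers the same way (−1.03). Of 22 elongation and pausing genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), the cyclin Ccnt2 (−1.02), and camera gave an adjusted p = 0.952 with its test pointing up at a mean of −0.05. Of 26 splicing factors 1 rose and 1 fell (1 and 1 adjusted over the list alone), Ptbp1 (1.03) and Rbm5 (−0.91), and camera gave −0.20 (adjusted p = 0.387).

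Metabolic and remaining lists were not called by camera. Glycolysis and hypoxia genes had 1 of 22 up and 0 down (1 and 0 adjusted over the list alone, mean 0.10, adjusted p = 0.382), the glucose transporter Slc2a1 (1.34), which is also a barrier gene. Oxidative phosphorylation genes had 0 of 16 past edgeR's threshold (0 adjusted over the list alone, 2 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom, mean 0.13, adjusted p = 0.184). Over 22 alternatives the adjusted p of that list (camera or fry) ranged from 0.00120 to 0.929, past the threshold in 2. Mesenchymal genes had 1 of 12 up and 0 down (3 and 1 adjusted over the list alone, mean 0.66, adjusted p = 0.0739, adjusted p = 0.410 with an estimated correlation), Vim (1.81), and camera called the list without Ctrl 3 (0.88, adjusted p = 0.0262) and without KO 3 (0.77, adjusted p = 0.0485), within a range of 0.00158 to 0.647 over 22 alternatives. Imprinted growth genes had 4 of 12 up and 1 down (4 and 1 adjusted over the list alone, mean 0.52, adjusted p = 0.158): the neighbours H19 (2.66) and Igf2 (2.08) rose, and Peg3 fell (−1.52).

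Of the 37 lists, camera called 24, 21 higher and 3 lower. With an estimated correlation 0 passed after Benjamini-Hochberg adjustment and 3 had an unadjusted p below 0.05, while fry called 11.

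Transcripts of the sex chromosomes separated the groups, while the labels do not give the sex of the pups. Counts of 4 genes of the Y chromosome (Kdm5d, Ddx3y, Eif2s3y and Uty) summed to 6, 7 and 3 in Ctrl 1, 2 and 3 and to 8035, 1457 and 1955 in KO 1, 2 and 3. Kdm5d had 0 counts in each Ctrl library and averaged 10.5 ± 5.48 CPM in KO (SD, n = 3), at least 53.9-fold higher than the highest Ctrl floor of 3 counts per library. Xist, expressed from the inactive X chromosome of females (NR_001463, chromosome X, 103460373 to 103483233), had 3174, 5058 and 3178 counts in Ctrl 1, 2 and 3 and 14, 111 and 1 in KO 1, 2 and 3. All libraries of 1 group thus differed in these genes from all libraries of the other, so that an effect of sex cannot be told apart from one of genotype in any comparison. Of the 1668 genes, 4 lie on the Y (of 4 tested) and 32 on the X (of 545 tested).

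In the authors' deposited table, 2255 genes were higher and 1357 lower in KO at their adjusted p threshold of 0.05, counted with the same entry per gene. All 1668 genes called here were among them with the same sign, and 96.2% of tested genes had the same sign in the authors' deposited table. The authors' deposited table also passed 6 of the genes tied to the question that did not pass here, with log2 fold changes of 0.93 for Flt1, 0.92 for Notch1, 1.60 for Nrarp, 1.43 for Esm1, 0.97 for Apln and 0.98 for Angpt2. For Rnf20 the authors' deposited table gave a log2 fold change of −0.58 with an adjusted p = 0.106.

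Because Rnf20 acts on transcription elongation, fold changes were set against gene length. Across genes, which are not independent replicates, longer genes tended to be lower in KO (Spearman's rho −0.208 with genomic span, in genes matched by expression decile), but 5 of the 10 splits of the 6 libraries, the real one included, gave a rho at least as large, up to 0.406. Without KO 3 rho was −0.119. Set against Ctrl, KO 1, 2 and 3 had a rho of 0.039, −0.234 and −0.362, and Ctrl 1, 2 and 3, each against the other Ctrl libraries, −0.267, 0.286 and 0.148. Transcript GC content gave a larger correlation, with a rho of 0.386 across 15837 genes, and 4 of the 10 splits, the real one included, gave one at least as large, up to −0.683. The slope on GC content was 0.01, −0.45 and −0.44 log2 units per 10 percentage points in Ctrl 1, 2 and 3 and −0.35, 0.65 and 0.59 in KO 1, 2 and 3.

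**Figure D4:**
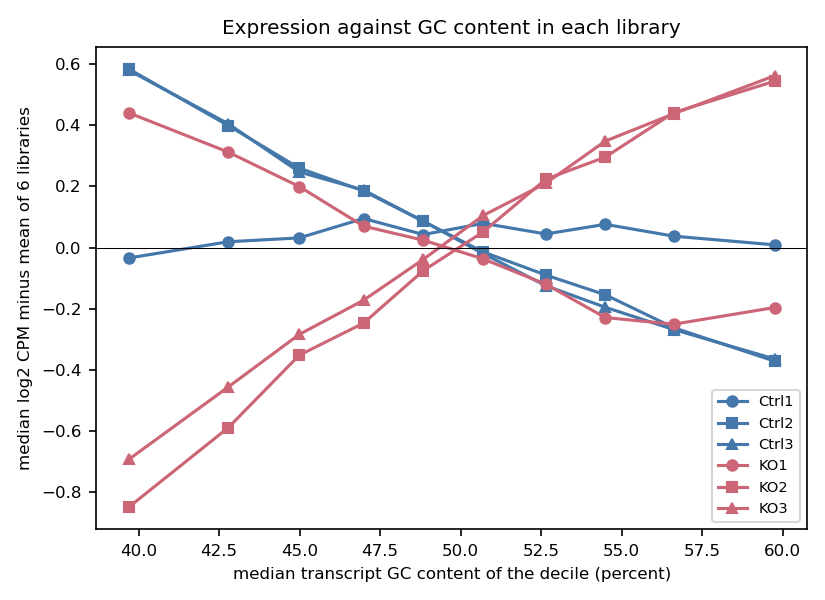
Median log2 CPM of each library, minus the mean of the 6 libraries, for genes in 10 bins of transcript GC content, where blue lines are Ctrl and red lines KO libraries. KO 2 and KO 3 rose with GC content (slopes 0.65 and 0.59 per 10 percentage points), while Ctrl 2, Ctrl 3 and KO 1 declined (−0.45, −0.44 and −0.35).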

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

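The tests of pup sex, of GC bias of single libraries, of Rnf20 genotype as the source of the GC trend and of loss of Rnf20 in female pups were chosen only after the results were seen.

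Many genes of the deposited table have several transcript entries, of which the gene-level comparison used 1. Of 6615 genes with another entry, 45 were called only through such an entry by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 30159 entries. They drew attention as a signal in data that the comparison left aside. The median adjusted p of their used entry was 0.0761.

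Gene lists of endothelium were higher in KO. The GC content trend does not account for this, since with GC offsets the endothelial markers stood at 0.98 above other genes, against 1.10 without. A larger share of endothelial RNA in the KO libraries may account for the endothelial lists. With libraries scaled to equal endothelial markers, 0 of 11 other endothelial lists rose by fry (1 fell, and at an unadjusted p below 0.05 0 rose and 4 fell). The erythroid list rose in the same fit, close to the threshold (fry, adjusted p = 0.0497). With GC offsets and that scaling the erythroid list had a mean of 1.39 and did not pass (fry, adjusted p = 0.0607). The 11 lists were grouped after the models had been fitted, and they hold 9 of the 15 markers that set the scaling. Without these markers 0 lists rose and 1 fell by fry (0 and 3 at an unadjusted p below 0.05), a check added after the result was seen. A larger endothelial share alone would lower the markers of all other cells alike, but these moved apart. Inner retinal neuron markers were at 4.23, 4.36 and 4.45 log2 CPM in Ctrl 1, 2 and 3 and 3.52, 3.46 and 4.14 in KO 1, 2 and 3, while erythroid markers were at 2.33, 2.80 and 3.40 in Ctrl and 5.76, 5.21 and 5.80 in KO, so it cannot be the whole account of the libraries.

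The sex of the pups and the genotype cannot be told apart for the endothelial lists either, because in 0 libraries do the Y transcripts go against the group. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes, the real split with 1668, and the highest of the others called 5. The splits are too few for a share under 0.05. An effect of Rnf20 loss on these genes within endothelial cells stays open.

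Genes of low GC content were lower in KO, with medians from −0.56 in the decile of lowest GC content to 0.63 in the highest. Whether Rnf20 genotype is the source cannot be told apart, since KO 1 had a GC slope of −0.35, within the range of the Ctrl libraries (−0.45 to 0.01), while KO 2 and KO 3 (0.65 and 0.59) lay above it, and 1 library excludes nothing. GC bias of single libraries may account for the trend, since KO 1 and KO 2, of 1 genotype, differed along GC content with a Spearman's rho of 0.594, against 0.386 for KO against Ctrl. The trend that the offsets remove is not the whole cause of the lower Zfp genes, whose mean was −0.97 relative to other genes and −0.74 with GC offsets. With the offsets camera gave an adjusted p = 1.50e-13, and an adjusted p = 0.201 with an estimated correlation. The offsets take off each library's trend over all genes, so a bias particular to this family is not excluded.

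Xist was nearly absent and Y transcripts were present in the KO libraries. Loss of Rnf20 in female pups does not account for this, since the lowest sum of Y gene counts in a KO library was 208 times the highest in a Ctrl library. Male KO pups and female Ctrl pups are a candidate explanation: 4 genes that escape X inactivation had a median log2 fold change of −0.72 relative to all genes (Kdm6a −1.71, Kdm5c −0.80, Eif2s3x −0.59 and Ddx3x −0.37, none past edgeR's threshold alone). Whether litters were sampled by sex is not given in the sources used here.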

How the results depend on the processing

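The scaling to endothelial markers, the marker covariates, the GC offsets and the choices of entries, chromosomes and list members were tests chosen only after the data were seen. Of 814 values of gene lists recomputed under the alternatives, 672 kept their direction and side of the threshold, 90 kept their direction without passing, 16 came to pass and 36 changed direction. Of 2493 values of 115 named genes other than Rnf20, the numbers were 1644, 778, 21 and 50. The number of genes changed lay between 1269 and 2101 in 12 alternatives, and the number of lists called by camera between 21 and 25 in 18. A similar number of genes need not mean the same genes. Among the 1668 genes called with all libraries, 1111 were called again in the same direction with GC offsets, against 1605 with limma-voom. Except where a value shows it, the cause was not tested.

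The number of genes changed was 3556 with DESeq2 (2027 higher, 1529 lower), 2690 with the photoreceptor marker level as a covariate (1418 lower), and 1 with the replicate number as a block (1 higher, 0 lower, 3407 at an unadjusted p below 0.05). With the endothelial marker level as a covariate it was 0 by edgeR (0 higher, 0 lower, 2916 at an unadjusted p below 0.05). That level did not overlap between the groups (7.10 to 7.73 log2 CPM in Ctrl, 8.33 to 8.89 in KO), so this fit can hardly separate it from genotype. The values showed no pairing by replicate number, since 0 of 6 libraries correlated best with the library of its own number. With 3 libraries per group this cannot exclude a shared litter or batch. GC offsets gave 1168 lower genes. Scaling to endothelial markers gave 6605 (77 higher, 6528 lower), and GC offsets with that scaling 8290 (62 higher, 8228 lower), as the scaling itself moves most genes down. The median of all genes moved to −1.16 and −1.18. Camera with an estimated correlation called 0 lists (3 at an unadjusted p below 0.05), fry 11, the endothelial covariate left 4 and the photoreceptor covariate 14.

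Leaving out each library in turn gave 0 to 4927 genes changed, 0 to 2520 higher and 0 to 2407 lower, an Rnf20 log2 fold change of −0.75 to −0.58, 21 to 25 lists and a rho with gene length of −0.302 to −0.119. Kdr ranged from −0.053 to 0.52, Jag1 from −0.40 to 0.88, the elongation list from −0.11 to −0.014, the unfolded protein list from −0.091 to −0.021, the progenitor list from −0.31 to 0.076 and the microglial list from 0.25 to 2.51.

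With libraries scaled to endothelial markers, Rnf20 passed at −1.83, and genes whose estimate was positive in the report became negative: Vegfa −0.49, Flt1 −0.35, Kdr −1.07, Notch1 −0.41, Hey1 −0.65, Jag1 −0.82, Apln −0.33, Angpt2 −0.37, Pecam1 −0.33, Mfng −0.12 and Ptbp1 −0.12. Of these, Kdr passed as lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0496, and 0.0266 with GC offsets too, range 0.0266 to 0.981 over 22 alternatives). Kdr, Flt1 and Pecam1, and below Eng and Tie1, are among the 15 markers that set the scaling. Markers that rose less than the others turn negative under it by construction, so their signs here are no separate evidence of a fall. With GC offsets and that scaling, Rnf20 passed at −1.72, and the values were Vegfa −0.56, Flt1 −0.40, Kdr −1.06, Flt4 −0.27, Notch1 −0.84, Hey1 −0.87, Jag1 −0.77, Apln −0.49, Angpt2 −0.23, Cldn5 −0.014, Pecam1 −0.38, Jag2 −0.39, Mfng −0.65, Ephb4 −0.062, Eng −0.10, Cdc20 −0.35, Ube2c −0.26, Bbc3 −0.55, Ptbp1 −0.41, Slc2a1 −0.13, Junb −0.60, Sdf2l1 −0.12, Nos3 −0.26, Tie1 −0.19, Nrgn −0.048 and Plvap −0.41.

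With the endothelial covariate, which does not overlap between the groups and is built in part from Flt1, Kdr and Pecam1, values changed sign in Rnf40 (0.33), Flt1 (−0.28), Kdr (−1.60), Jag1 (−1.29), Esm1 (−0.66), Pecam1 (−0.81), Birc5 (−0.059), Pde6b (0.14) and Sag (1.42). With the photoreceptor covariate this held for Kdr (−0.75) and Jag1 (−0.97).

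List directions follow camera's test, so that a mean can keep its sign where the test turns. With the endothelial covariate the test turned for the VEGF (0.13), venous (−0.45), barrier (−0.26), DNA replication (−0.66), basement membrane (−0.15), interferon (−0.37), unfolded protein (−0.088), angiopoietin (−0.31), mesenchymal (−0.66), mural (−1.03), photoreceptor (1.19) and progenitor (0.95) lists. This covariate can hardly be separated from genotype. The mitosis list, whose estimated correlation without it was 0.78 against camera's preset 0.01, turned and passed (−1.55, camera, adjusted p = 2.04e-05, range 2.04e-05 to 0.704 over 22 alternatives), and the BMP list had a mean of −0.25 while its test pointed up. With the photoreceptor covariate it turned for the mitosis (−0.34), photoreceptor (−0.0078) and progenitor (0.17) lists, with scaling to endothelial markers for elongation (−0.061), oxidative phosphorylation (0.13), unfolded protein (−0.032) and progenitors (−0.13), and with GC offsets for elongation (−0.075) and splicing (0.045). With GC offsets and scaling it turned for Notch (0.10), elongation (−0.088), glycolysis (−0.058) and unfolded protein (−0.083), with fry for progenitors (−0.023), with genes overlapping no other gene for unfolded protein (−0.079) and lymphatic endothelium (0.051), and without a low-count filter for unfolded protein (−0.093).

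In the simulations, 4-fold changes were recovered in 38.1% and 2-fold changes in 0.4% of cases, so that genes short of the threshold are not shown to be unchanged. Each simulation changed 100 genes by each size, far fewer than the 1668 called here, which makes the adjusted threshold stricter. These rates therefore do not give the share of real changes recovered.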

Other observations

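Rn45s and the gene families below were chosen only after the results were seen. The tests of gene length were not, but the GC offsets that the last of them uses were chosen after the data were seen. The reading of the first of them was changed afterwards. Rn45s, the 45S precursor of ribosomal RNA, was 6.27-fold higher in KO, at 7124, 9385 and 8530 CPM in KO 1, 2 and 3 against 1367, 1346 and 1281 CPM in Ctrl 1, 2 and 3 (SE 0.250 for an Rn45s log2 fold change of 2.65). It passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0206, range 5.36e-20 to 0.262 over 20 alternatives, of which it passed 14), but not without Ctrl 1 (adjusted p = 0.0801), Ctrl 2 (0.112), Ctrl 3 (0.107) or KO 2 (0.0859), where 0 genes passed and its log2 fold change was 2.67, 2.66, 2.62 and 2.58 (0 genes by edgeR, with 4005, 3434, 3479 and 3576 at an unadjusted p below 0.05). The libraries were made from polyadenylated RNA, so these reads are no measure of the synthesis of ribosomal RNA. Whether the rise came from the cells or from the preparation was not tested.

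Zfp zinc finger genes were lower as a family, with 3 of 359 up and 72 down and a mean of −0.97 relative to other genes (camera, adjusted p = 1.49e-16, adjusted p = 0.144 with an estimated correlation). Ribosomal protein genes were higher, with 33 of 80 up and 0 down (0.89, camera, adjusted p = 1.04e-15, adjusted p = 0.144 with an estimated correlation). MHC genes had 6 of 29 up and 0 down (1.67, camera, adjusted p = 3.74e-08, adjusted p = 0.196 with an estimated correlation), and chemokines 6 of 22 up and 0 down (1.86, camera, adjusted p = 0.000122, adjusted p = 0.303 with an estimated correlation). Microglial and macrophage markers, whose cells express both families, averaged 1.95, and without KO 2 these markers stood at 0.25, MHC genes at 1.27 and chemokines at 1.13. Protocadherins had 1 of 69 up and 16 down (−0.51, camera, adjusted p = 0.0131, adjusted p = 0.364 with an estimated correlation), where markers of photoreceptors (−1.03) and inner retinal neurons (−0.71) were lower too. These 5 families kept the sign of their mean relative to other genes in 22 alternatives, from −1.16 to −0.74 for Zfp genes, 0.77 to 1.56 for ribosomal proteins, 1.27 to 1.86 for MHC genes, 1.13 to 2.28 for chemokines and −0.78 to −0.39 for protocadherins. Kinesins stood at −0.29 with 1 of 35 up and 2 down (camera, adjusted p = 0.0470, adjusted p = 0.357 with an estimated correlation), and were not called with GC offsets (−0.30, 0 up and 6 down, camera, adjusted p = 0.0650). Collagens stood at 0.32 with 5 of 39 up and 0 down (camera, adjusted p = 0.0470, adjusted p = 0.196 with an estimated correlation), but at −0.16 with the endothelial marker level as a covariate, and at 0.033 with GC offsets, where 0 were up and 2 down (camera, adjusted p = 0.788). Solute carriers went both ways, with 15 of 293 up and 11 down (0.05, camera, adjusted p = 0.453).

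A hypothesis was that loss of Rnf20, which acts on elongation, lowers longer genes. The test was to exclude this if any KO library had a rho with genomic span at or above that of some Ctrl library, as KO 1 (0.039) and KO 2 (−0.234) did against Ctrl 1 (−0.267), and KO 3 (−0.362) did not. KO 2 did so by less than the SD of the Ctrl libraries (0.288), so that beyond this spread the bound was met by 1 library, which excludes nothing, and an effect of Rnf20 genotype cannot be told apart from the spread between libraries. That SD is a rough guide. Each Ctrl value was taken against the other Ctrl libraries and so depends on them, while the KO values were taken against all Ctrl libraries. The GC content trend between libraries may contribute: with GC offsets the rho was −0.0894, against −0.208 without, which is neither near 0 nor most of its size, so that its share cannot be told apart.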
